A study of Frankia alni ACN14a with 21 samples.

How the data were processed

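Frankia alni ACN14a, a filamentous actinobacterium that fixes nitrogen in root nodules of trees, was profiled on 1-colour NimbleGen oligonucleotide arrays labelled with Cy3. Per the labels, free-living cells were grown for 5 days in a propionate medium with 5 mM ammonium, and nodules were collected 3 to 4 weeks after inoculation. Experiment A comprised 15 arrays, 3 for each of 5 groups: free-living cells and nodules of 2 Myrica species, M. rubra and M. gale, and of 2 Alnus species, A. nepalensis and A. glutinosa. Experiment B was made in another laboratory on another array platform and comprised 6 arrays, 3 of free-living cells and 3 of Alnus glutinosa nodules. Each array was a biological replicate, per the series' design text. RNA was prepared with CTAB in experiment A and with a column kit in experiment B, and 3 times the usual amount of cDNA was used for nodules, per the labels' protocols. Groups were taken from the sample labels.

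Both deposited value tables hold 1 linear intensity for each of 6607 locus tags, made with RMA per the submitters' processing notes; the version and the background model are not given in the sources used here. The array medians of these deposited intensities lay between 125 and 131 in experiment A and between 196 and 208 in experiment B. RMA values are usually given as log2; these were on a linear scale, and log2 was taken before testing. For experiment B the scanner files were used: per the file headers, NimbleScan 2.4.31 extracted 389307 spot intensities per array, neither background-corrected nor normalized. They cover the 6607 locus tags (18 probes each for 6340 of them, 2 spots per probe), 2975 regions named by start and end coordinates, 23 other sequences and 66425 spots of random control probes. The deposited table of experiment B, set against the rebuilt gene values array by array, gave correlations across genes between 0.983 and 0.989, so its scale is linear and its direction is that of the scanner values. No scanner files of experiment A were at hand, so its background and its slides stayed unknown.

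In experiment B the probe intensities were corrected with normexp (offset 50), taken to log2 and quantile-normalized between the 6 arrays without the random probes. Spots of a probe were averaged, and probes of a gene were summarised by median polish. Genes, and separately regions with other sequences, were then tested. The background limit of each array was the 95th percentile of 1000 sets of 18 random probes summarised as genes are. This limit for gene values was chosen after the data were examined; the planned limit from single random probes was kept as an alternative filter. A gene on no array of a group above it is given as at least N-fold, from the bright group's mean over the higher of the dim group's own value and the limit on each array, as means of normalized log2 values.

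Tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3 with 1 coefficient per group, and Benjamini-Hochberg adjustment over all features. Genes at an adjusted p under 0.05 were called. The 15 arrays of experiment A were fitted together, the 6 of experiment B apart, because the tables were normalized separately; only fold changes are set side by side. Among hosts a moderated F test was used. Arrays give no counts, so their number limits the precision. The steps were tested on simulated data with 100 genes changed by each fold among all genes. For the mean of 4 hosts in experiment A, 100% of changes of 2-fold were recovered. These changes were added to log2 gene values without a background, so a high recovery was likely beforehand. Experiment B was simulated from probe intensities with a background. There 60% of 2-fold and 88% of 4-fold changes were recovered, and the median fitted fold of the 4-fold changes was 2.16. The recoveries of the experiments therefore cannot be set against one another, and compression by background in experiment A was not tested.

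The files do not pair locus tags with gene names, and no annotation was used here. Gene lists for pathways and a centring on ribosomal protein genes, both planned before the data were examined, therefore could not be run, and no gene is named beyond its tag. The rule for named genes took the largest rises and falls among called genes (for the mean of 4 hosts, among genes called the same way in each host; for Alnus against Myrica, among genes whose arrays did not overlap). It foresaw up to 12 genes each way; for want of names at most 2 each way are printed per comparison. Alternatives tried were background correction, normalization, probe summary, filters on dim genes, a 2-fold minimum, array weights, a variance trend, centring, a pseudocount of 16, the replicate number as a block, fits of 2 groups alone, and leaving out each array.

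In experiment B all free-living arrays were extracted in 1 session, from images with a grid about 2596 pixels wide, and all nodule arrays in another session, with a grid of 764 pixels. About 11.1% of the free-living spot intensities were whole numbers, against 100% on nodule arrays. Extraction session and group therefore cannot be told apart in experiment B.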

Results

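Transcript levels of Frankia alni ACN14a were measured in free-living cells supplied with ammonium and in young nodules of 4 tree species, with 3 arrays per group. Experiment A held 15 arrays of 5 groups and experiment B 6 arrays of 2 groups. Within groups of experiment A the arrays correlated across genes between 0.967 and 0.990, whereas free-living arrays correlated with nodule arrays between 0.730 and 0.810. Arrays of Alnus nodules correlated with arrays of Myrica nodules between 0.925 and 0.958. No 2 replicates were copies of one another, since at most 0.0303% of their values were identical. In experiment B the median intensity of locus-tag probes was 1.03 to 1.06 times that of random control probes on free-living arrays and 1.12 to 1.13 times on nodule arrays. A background limit could be set for experiment B alone. In experiment A, where array medians lay between 125 and 131, the size of a change is not exact for a gene whose mean in either group lay below them.

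The first question was which genes of the bacterium changed between free-living growth and symbiosis. Averaged over the 4 hosts, FRAAL6813 and FRAAL6812 had the largest fitted rises and FRAAL5638 and FRAAL1946 the largest fitted falls. Their order is not exact, since the rises ended near the top of the scale and FRAAL5638 ended below the array medians. The log2 change of FRAAL6813 was 8.62 ± 0.12 (SE), a measured rise of 394-fold with an adjusted p of 5.17e-24 (limma), and that of FRAAL6812 was 8.52 ± 0.13. Both fitted rises may be too small, because FRAAL6813 on 9 and FRAAL6812 on 8 of the 12 nodule arrays lay within 5% of the highest value of the array. FRAAL5638 fell by 6.74 ± 0.15 on the log2 scale and FRAAL1946 fell by 6.64 ± 0.12. For each of these 4 genes, all 12 nodule arrays lay beyond all 3 free-living arrays. FRAAL6813 went from a mean log2 intensity of 7.28 ± 0.11 (SD, n = 3) in free-living cells to between 15.75 and 15.98 in the nodules. FRAAL5638 went from 13.16 ± 0.20 in free-living cells to between 6.35 and 6.50 in nodules, below the median of every array; how near this is to background is not known in experiment A. In total, 1476 genes were called higher and 1617 lower in nodules, of 6607, and 484 and 688 of them changed at least 2-fold. FRAAL6813 and FRAAL6812 lie in an unbroken run of 21 tags, next to one another by number among the tags on the array, that were all called higher in each of the 4 hosts, with a median log2 change of 5.67 and a range from 1.80 to 8.62. This run was picked out after its values were seen.

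**Figure D1:**
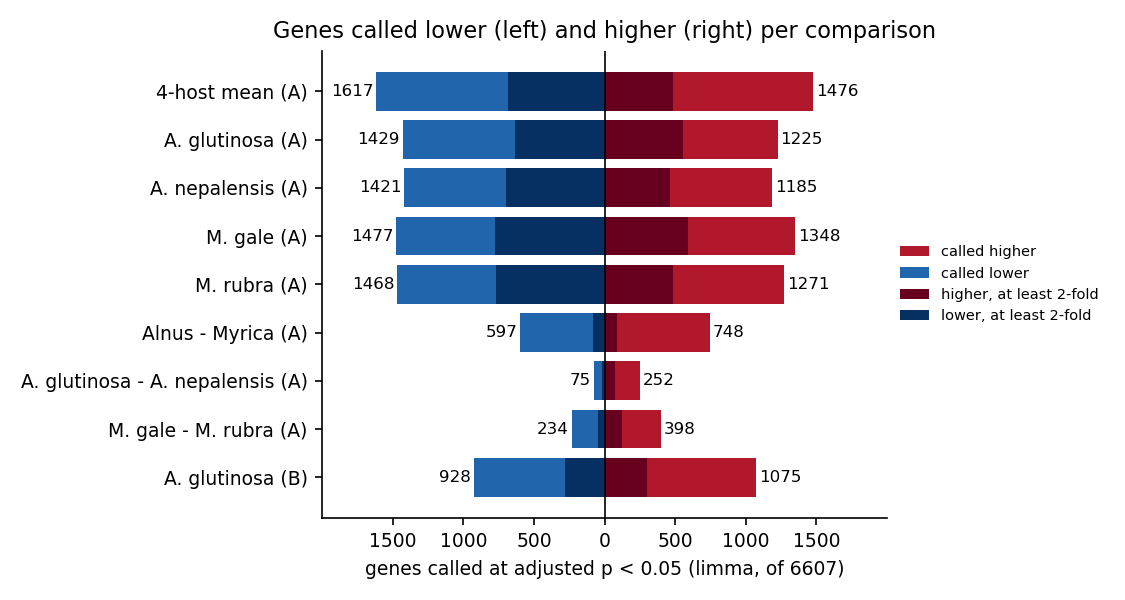
Number of genes called lower (left, blue) and higher (right, red) at an adjusted p under 0.05 for each comparison, with the darker parts at 2-fold or more. Nodule comparisons of experiment A called between 2606 and 3093 genes each, and the 2 comparisons within a genus 327 and 632.

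Each host was then compared with free-living cells on its own. In Alnus glutinosa nodules 1225 genes were called higher and 1429 lower, in Alnus nepalensis 1185 and 1421, in Myrica gale 1348 and 1477, and in Myrica rubra 1271 and 1468. FRAAL6813 and FRAAL6812 had the largest fitted rises in 3 of these hosts. In Alnus glutinosa FRAAL6811 was close to them, at 8.58 ± 0.20, so the order there is not known. FRAAL6813 rose by 8.63 ± 0.15 on the log2 scale in Alnus glutinosa, 8.47 ± 0.15 in Alnus nepalensis and 8.69 ± 0.15 in Myrica rubra. In Myrica gale the largest fitted rises were FRAAL6811, at 8.80 ± 0.20, and FRAAL3855, at 8.74 ± 0.18, while FRAAL6813 stood at 8.70 ± 0.15. Since FRAAL6813 was limited by the top of the scale, the order of these genes is not known. The free-living mean intensities of FRAAL6811 (96.9) and FRAAL3855 (116) lay below the array medians, so the sizes of their rises are not exact. FRAAL5638 had log2 changes of -6.73 in Alnus glutinosa, -6.81 in Alnus nepalensis, -6.66 in Myrica gale and -6.78 in Myrica rubra (SE 0.19 each), all against the same free-living mean and all with low nodule values, so that neither their size nor their closeness is exact. FRAAL1946 had a log2 change of -5.90 ± 0.15 in Myrica gale and of -7.03 ± 0.15 in Alnus nepalensis, where its nodule mean lay below the array medians. The log2 change of FRAAL5525 was -7.61 ± 0.24 in Myrica gale and -6.90 ± 0.24 in Myrica rubra, against -4.73 ± 0.24 in Alnus glutinosa and -5.48 ± 0.24 in Alnus nepalensis; in Myrica gale its mean, too, lay below the array medians. The difference of FRAAL5525 between the 2 Alnus and the 2 Myrica hosts was itself called, at 2.14 ± 0.17 higher in Alnus.

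A common set of 1642 genes was called with the same sign in all 4 hosts, 652 higher and 990 lower. At least 2-fold in each host, 289 were higher and 492 lower, and 23 and 17 changed at least 16-fold in each. Lists of the sizes called in each host, before any minimum fold, would share by chance 8.62 genes higher and 15.3 lower. Because the 4 contrasts use the same 3 free-living arrays, unchanged groups were also simulated against shared controls: the highest number called in all 4 was 0 in 100 simulations. No gene was changed there, so few calls are expected in any contrast. The 0 therefore does not size the calls shared through the controls. The changes in pairs of hosts correlated across genes between 0.898 and 0.944, against 0.500 for unchanged groups, and their covariance was 0.931 to 1.11 against 0.0168. With 3 free-living arrays the controls could not be split into sets of at least 2. The simulated 0.0168 already holds the array noise of the shared controls. The observed 0.931 to 1.11 therefore argues against that noise as the main source of the excess. A departure common to all 3 free-living arrays would still enter all 4 contrasts and stays open. Only 86 genes were called higher in at least 1 host and lower in another.

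**Figure D2:**
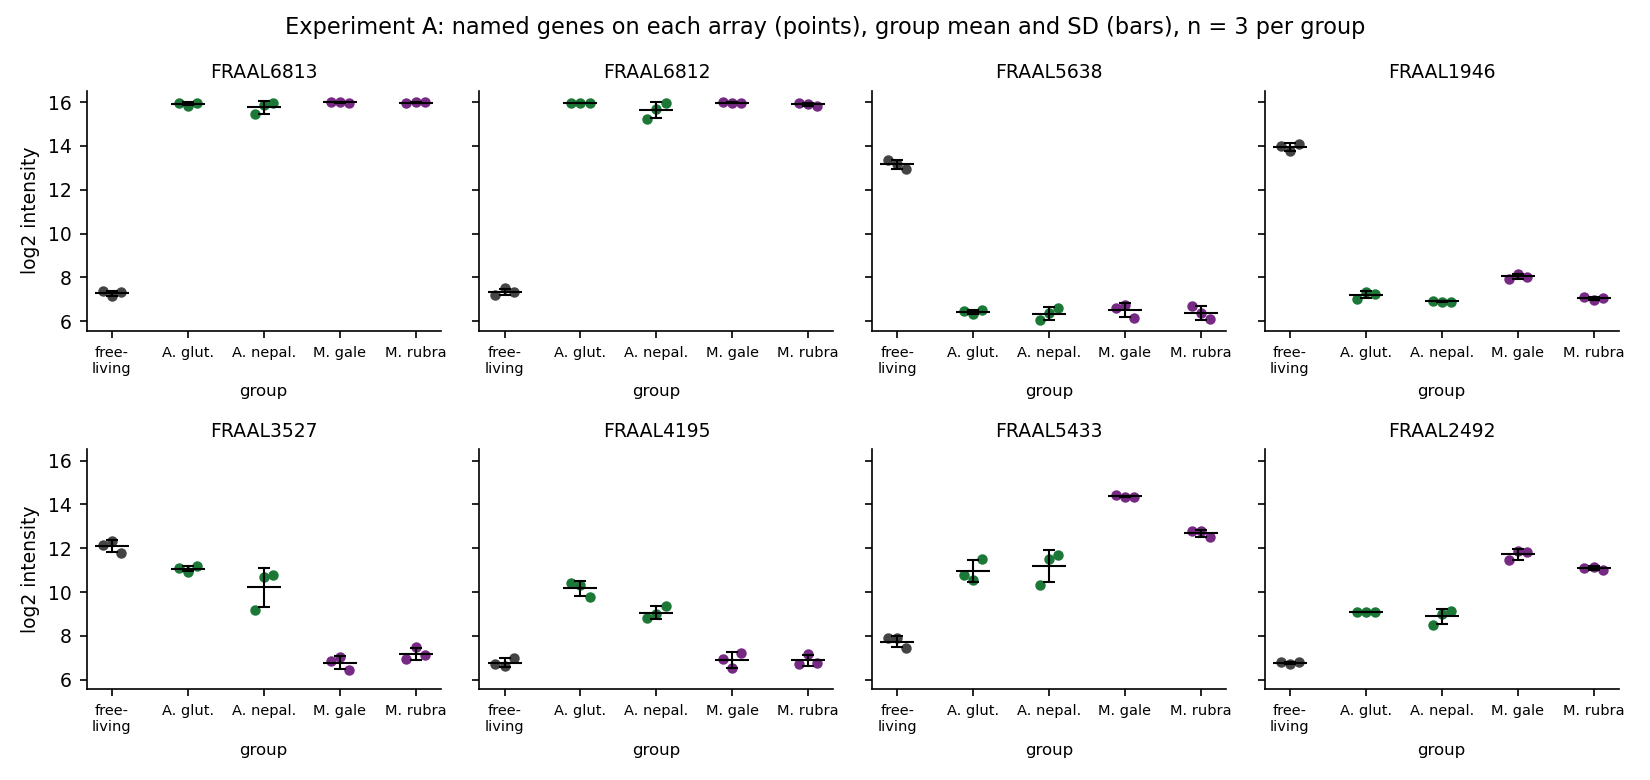
Log2 intensity (vertical axis) of 8 named genes on each array of experiment A by group (horizontal axis), with green for Alnus, purple for Myrica and grey for free-living cells; bars give the mean and SD of 3 arrays. FRAAL6813 and FRAAL6812 are near 16 in all nodules, and the lower row shows genes named because the 6 Alnus and the 6 Myrica arrays did not overlap.

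**Figure D3:**
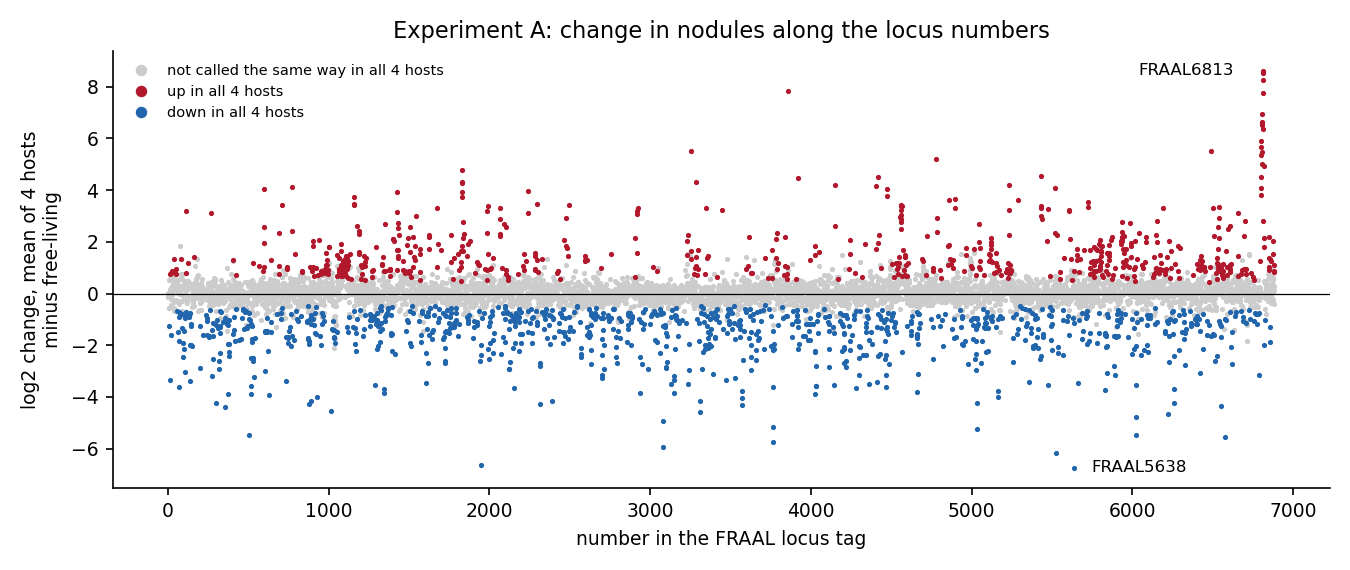
Mean log2 change of the 4 hosts against free-living cells (vertical axis) for each gene by the number in its FRAAL tag (horizontal axis); red and blue mark genes called higher and lower in all 4 hosts. The peak at the right edge is the run that holds FRAAL6813, which reaches 8.62.

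The next comparison asked whether the nodule host made a difference. FRAAL3527 and FRAAL4195 were the genes furthest above in Alnus nodules, and FRAAL5433 and FRAAL2492 those furthest above in Myrica nodules. The SE and adjusted p of these differences rest on the spread of arrays within hosts. They do not measure the spread between species, of which each genus had 2. FRAAL3527 was higher in Alnus by 3.66 ± 0.20 on the log2 scale, 12.7-fold (limma, adjusted p = 1.69e-11). Its mean log2 intensity was 12.09 ± 0.27 in free-living cells, 11.07 ± 0.12 in Alnus glutinosa and 10.22 ± 0.90 in Alnus nepalensis nodules, but 6.78 ± 0.30 in Myrica gale and 7.18 ± 0.27 in Myrica rubra nodules (SD, n = 3). FRAAL4195 was higher in Alnus by 2.72 ± 0.15. Against free-living cells its log2 change was 3.39 ± 0.21 in Alnus glutinosa and 2.28 ± 0.21 in Alnus nepalensis, and 0.11 ± 0.21 in both Myrica hosts, which were not called. FRAAL5433 rose in all hosts, by 3.21 ± 0.27 and 3.44 ± 0.27 in Alnus glutinosa and Alnus nepalensis and by 6.63 ± 0.27 and 4.95 ± 0.27 in Myrica gale and Myrica rubra. FRAAL3527 in Myrica gale nodules, FRAAL4195 in Myrica nodules and free-living cells, and FRAAL2492 in free-living cells lay below the array medians. The Alnus minus Myrica difference was -2.46 ± 0.19 for FRAAL5433 and -2.42 ± 0.12 for FRAAL2492. The rule for naming genes took only those whose 6 arrays of a genus lay beyond all 6 of the other, so their separation is not a finding.

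Altogether 748 genes were called higher in Alnus and 597 higher in Myrica nodules, of which 88 and 86 differed at least 2-fold. These calls, too, rest on the spread of arrays within hosts, so they hold for these species and not for the genera at large. Of the called genes, 327 rose in both genera and 325 fell in both, so that they differed in the size of the change. Over all genes the Myrica changes had an orthogonal slope of 1.10 on the Alnus changes. Of 1098 genes called in all 4 hosts and changed at least 2-fold on average, 712 (64.8%) changed more in Myrica. A moderated F test among the 4 hosts called 1750 genes (26.5%).

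**Figure D4:**
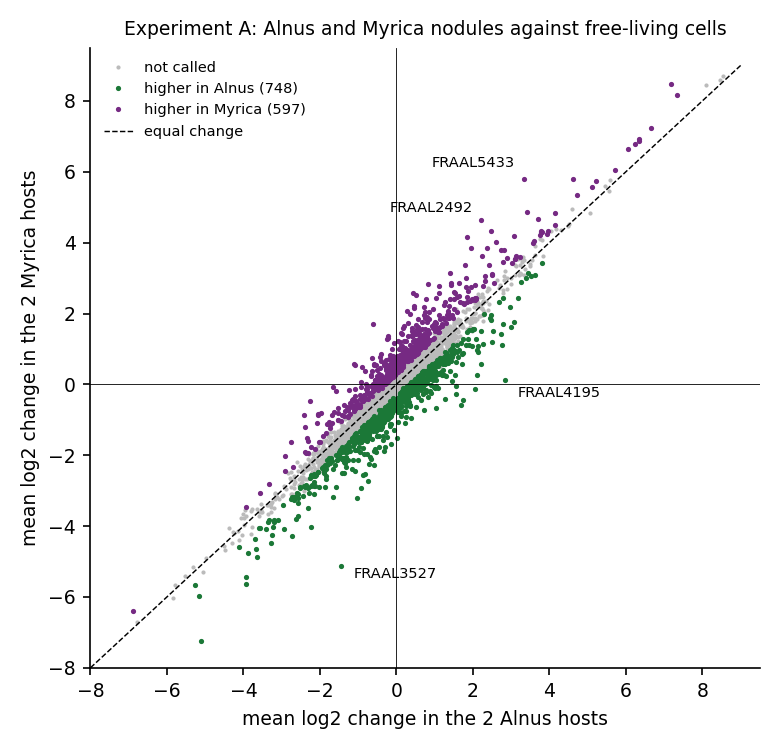
Mean log2 change against free-living cells in the 2 Myrica hosts (vertical axis) and the 2 Alnus hosts (horizontal axis), 1 point per gene; green and purple mark the 748 genes called higher in Alnus and the 597 called higher in Myrica, and the dashed line marks equal change. The labels mark FRAAL3527 and FRAAL4195 below the line and FRAAL5433 and FRAAL2492 above it.

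Hosts of the same genus were compared with 3 arrays against 3, where the genera had 6 against 6, so the counts of called genes cannot be set against one another directly. In Alnus glutinosa against Alnus nepalensis nodules 252 genes were called higher and 75 lower. FRAAL4282 was higher in Alnus glutinosa by 2.94 ± 0.24 on the log2 scale and FRAAL3036 by 2.76 ± 0.21. FRAAL0407 was lower there by a log2 difference of -3.01 ± 0.26 and FRAAL6291 by -2.81 ± 0.26. Without Alnus nepalensis replicate 1 the differences were -2.68 for FRAAL0407, -2.43 for FRAAL6291 and 2.53 for FRAAL4282, the smallest when any array was left out. That of FRAAL3036 was smallest, 2.58, without Alnus glutinosa replicate 1. FRAAL3036 had a mean log2 intensity of 9.22 ± 0.43 (SD, n = 3) in Alnus glutinosa nodules and between 6.30 and 6.46 in the other hosts. FRAAL6291 stood at 9.43 ± 0.66 in Alnus nepalensis nodules and between 6.62 and 7.23 in the others. The values of FRAAL3036 in Alnus nepalensis and of FRAAL6291 in Alnus glutinosa lay below the array medians, so these 2 differences are not exact. The count of 327 fell to 214, 192 and 172 without Alnus glutinosa replicate 1, 2 or 3 and to 208 without Alnus nepalensis replicate 2, and rose to 851 with array weights.

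In Myrica gale against Myrica rubra nodules 398 genes were called higher and 234 lower. At least 2-fold, 124 were higher and 50 lower. FRAAL4989 and its neighbour FRAAL4990 were higher in Myrica gale by 4.65 ± 0.30 and 4.14 ± 0.21 on the log2 scale. FRAAL4990 had a mean log2 intensity of 11.45 ± 0.11 (SD, n = 3) in Myrica gale nodules and between 7.31 and 8.39 in the other nodules. FRAAL5486 and FRAAL2360 were higher in Myrica rubra, with log2 differences of -3.82 ± 0.23 and -2.95 ± 0.22. FRAAL5486 stood at 12.02 ± 0.60 in Myrica rubra nodules and between 7.72 and 8.20 in the other nodules. FRAAL4282, named above for the Alnus hosts, was also higher in Myrica gale than in Myrica rubra, by 3.42 ± 0.24.

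The comparison of Alnus glutinosa nodules with free-living cells was made again in the other laboratory, as experiment B. FRAAL6812 and FRAAL6813 were again the largest rises. FRAAL6812 was not above the background limit on any free-living array and rose at least 65.9-fold (limma, adjusted p = 6.10e-09), with all 3 nodule arrays above all 3 free-living arrays. FRAAL6813, above the limit on 2 of 3 free-living arrays, rose by 6.01 ± 0.15 on the log2 scale. FRAAL3765 was not above the limit on any nodule array and was at least 26.5-fold lower there. Its neighbour FRAAL3764 fell by 5.37 ± 0.24 on the log2 scale, from a mean of 14.15 ± 0.56 to 8.79 ± 0.06 (SD, n = 3). In experiment A their log2 changes in Alnus glutinosa were -5.87 ± 0.26 for FRAAL3765 and -5.11 ± 0.22 for FRAAL3764. The nodule mean of FRAAL3765 lay below the array medians there, so the size of its fall is not exact. In total 1075 genes were called higher and 928 lower, with 302 and 282 of them at a fitted change of at least 2-fold. Random probe sets were also lower in nodules, with a median log2 change of -0.167. Of 1000 such sets 19 were called lower and 0 higher, none of them at 2-fold or more. Small falls of genes near background are therefore not exact, and some of the 928 may not be falls of the genes themselves. With median scaling in place of quantile normalization 1428 were higher and 752 lower. Of the 1083 genes with a value above single random probes on any array 754 were called, a lower count because fewer genes were tested. Of 23 other sequences on these arrays 20 were called higher in nodules, 1 lower, and 2 were not called; the median scanner intensity of their probes was 1136 to 1416 on free-living arrays and 31861 to 56404 on nodule arrays. Extraction session and group coincided in this experiment.

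Both experiments were set side by side for Alnus glutinosa, gene by gene. The log2 changes correlated with a Pearson r of 0.724 and a Spearman rho of 0.611 across 6607 genes, which are not independent replicates. Of 2654 genes called in experiment A, 2221 (83.7%) had the same sign in experiment B and 1276 (48.1%) were called there with the same sign. Genes called higher in both numbered 675 and genes called lower in both 601, where independent lists would share 199 and 201. The limit given above for small falls in experiment B holds for the 601 too. The controls of the 2 experiments were separate. The changes were smaller in experiment B, with a slope of 0.572 on those of experiment A. This and the other slopes of B on A are orthogonal slopes, which treat both experiments alike. FRAAL6813 had a log2 change of 8.63 ± 0.15 in experiment A and 6.01 ± 0.15 in experiment B, and FRAAL5638 changed by -6.73 ± 0.19 and -1.73 ± 0.29. In the nodules of experiment B FRAAL5638 was not above the background limit, so its fall there was at least 2.16-fold.

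**Figure D5:**
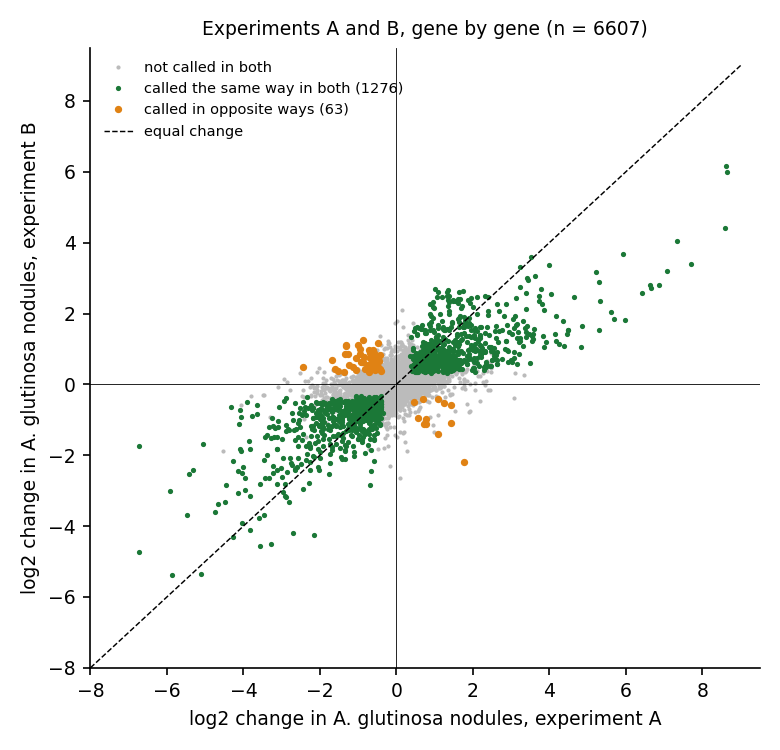
Log2 change in Alnus glutinosa nodules in experiment B (vertical axis) and experiment A (horizontal axis), 1 point per gene; green marks the 1276 genes called the same way in both, orange the 63 called in opposite ways, and the dashed line equal change. The orthogonal slope of the points is 0.572, below that of the dashed line.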

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

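Some tests of this part were chosen or reworded after results were seen. The test on random probe sets was chosen after its result was seen. The test of array slopes was planned for the larger changes in Myrica and was turned to the differences between the genera once its value was known, and a further test, the share of calls with opposite directions in the 2 genera (1.26%), was dropped then because it bore on no technical explanation. The slope over the brightest genes was chosen after the other slopes were seen, and the set of genes above background was redefined after correlations over a similar set were seen. Groups of 3 arrays are too small to single out an outlying array.

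The changes against free-living cells differed between hosts, as tested by the contrasts themselves: 1345 genes between Alnus and Myrica, 1750 among the 4 hosts, 327 between the Alnus hosts and 632 between the Myrica hosts. The 1345 calls rest on the spread of arrays within hosts, not on that between species of a genus. Among them 17 genes were called in opposite directions against free-living cells in the 2 genera. Of these, chosen after their values were seen, FRAAL2286 had a log2 change of 1.68 in Alnus and -0.58 in Myrica nodules (difference 2.26 ± 0.15), and FRAAL6145 one of 1.27 and -0.41. In the other direction FRAAL1636 had -1.11 in Alnus and 0.56 in Myrica nodules, and FRAAL5486 had -0.62 and 1.69, its Myrica value coming from Myrica rubra (3.60 ± 0.23) rather than Myrica gale (-0.22 ± 0.23). One technical explanation of the differences between the genera is a stretching of all changes on the Myrica arrays, whose slopes on the mean change were 1.01 to 1.07 against 0.941 to 0.970 on Alnus arrays. After each array's changes were divided by its own slope, 1110 of the 1345 calls (82.5%) were left, which argues against stretching as the whole source of the differences, though not of the larger size of the changes in Myrica. Different hybridisation of plant cDNA in the 2 genera stays open, since no random probes of experiment A were analysed, and the host itself stays open as a biological explanation, untested.

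Data outside the comparisons also carried signal. Of 23 sequences on the arrays of experiment B that are not locus tags, 20 were called higher in nodules, 1 was called lower (log2 change -0.56 ± 0.16) and 2 were not called. The sequence called lower was not above the background limit on any array of either group, so its change is not exact. Among those called higher, 1 is named on the array as an Alnus cinnamoyl-CoA reductase. The rest carry only database identifiers, whose organism is not stated. For the 11 of them that were at background on all free-living arrays and above it on all nodule arrays, the rises were at least 3.34-fold to at least 99.7-fold. Among 2975 regions named by coordinates, for which the build and the annotation are not given in the sources used here, 412 were higher and 677 lower in nodules. The region from 7418937 to 7419135 was at least 32.7-fold higher, and the region from 4337425 to 4337515 fell by 5.22 ± 0.19 on the log2 scale.

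Because nodule RNA holds plant RNA, and more nodule cDNA was applied, the rises of the genes called in all 4 hosts may owe something to unspecific hybridisation. Plant cDNA that met single probes by chance would raise few probes of a gene. For the 289 genes up at least 2-fold in all 4 hosts of experiment A, however, a median of 94.4% of a gene's own probes were higher in the nodules of experiment B (quartiles 88.9% and 100%), where genes not called in all 4 hosts had quartiles of 33.3% and 66.7%. Unspecific hybridisation to any probe would raise random probes too: 0 of 1000 random probe sets, 0%, were called higher by limma (11 at an unadjusted p under 0.05), against 16.3% of genes, and 19 were called lower (189 unadjusted). The share shows that these rises spread over a gene's probes in Alnus glutinosa. Gene values combine all probes, however, so genes raised at few probes could hardly enter the set. A high share was likely beforehand. The random sets did not rise relative to the other probes. A rise common to all probes is removed by normalization, so it could not show there. These 2 explanations are thus not excluded. Plant transcripts alike along a whole gene, and the other 3 hosts, were not tested. Symbiotic growth stays open as a biological explanation, but ammonium supply, medium and age differed along with it and cannot be told apart from it.

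In the 2 laboratories 63 genes were called in opposite directions in Alnus glutinosa, with every nodule array on the side of its own experiment. Such a separation was likely for genes already called. Higher in experiment A and lower in B were 12 genes, where independent lists would share 172. The other way there were 51, where such lists would share 233. Opposite calls were thus fewer than independent lists would give. The difference between the experiments was not tested, since the tables were normalized apart. FRAAL1882, chosen after its values were seen, had a log2 change of 1.77 ± 0.43 in experiment A and -2.20 ± 0.19 in experiment B. The smaller changes in experiment B were weighed against 3 explanations; compression by its background and processing together stays open, since 4-fold changes simulated with a background came back at a median of 2.16-fold. Over the 2385 genes with a mean above the background limit the orthogonal slope of B on A was 0.603 (95% bootstrap interval over genes 0.574 to 0.637). Over the genes with a mean not above it the slope was 0.409. Genes dim by their mean alone thus do not account for the smaller changes. The brighter set still held genes with 1 group at background, such as FRAAL6812, so compression of such genes is not excluded. With an offset of 0 in the background correction the slope over all genes was 0.653 (0.626 to 0.682), so the offset alone does not account for the smaller changes either. Background light under all genes cannot be told apart from other causes: over the 660 brightest genes the slope was 0.763 (0.718 to 0.815), between the values that would have spoken for it and against it, and the extraction session coincides with the group, while laboratory, RNA method and array platform also differ and stay open, untested.

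Other splits of the arrays were fitted as 2 groups, or with permuted groups for the last pair of results. Among 100 splits of the 15 arrays into 12 and 3, the real one called 2564 genes and the highest other 15, and 1 of 100, the real one, called as many. For Alnus against Myrica, 1 of 100 splits called as many as the real 841, and the highest other called 0. For genes changed in all 4 hosts (real 1642, highest other 7) and for the F test among hosts (real 1750, highest other 258), 1 of 100 permutations, the real one, reached the real count. For these 4, no other split or permutation drawn reached the real count. Other splits mix unlike groups, which widens the spread within them, so low counts were likely beforehand. Chance is therefore not excluded by them. The genera hold 2 hosts each, however, and whole hosts pair in only 3 ways, too few for a share under 0.05; in the fit of all arrays the pairing by genus called 1345 genes, Alnus glutinosa with Myrica gale against the other hosts 768, and Alnus glutinosa with Myrica rubra against the other hosts 363. The comparison of whole hosts was added after the results were seen. Comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05; the real and highest other counts were 2717 and 0 in Alnus glutinosa, 2277 and 0 in Alnus nepalensis, 2718 and 0 in Myrica gale, 2358 and 0 in Myrica rubra, 456 and 2 between the Alnus hosts, 565 and 0 between the Myrica hosts, and 2003 and 0 in experiment B.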

How the results depend on the processing

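Under the alternatives, all 540 values of the named genes kept their direction and their side of the threshold. Named genes were picked as the largest called changes, so this was likely beforehand and does not speak for the other called genes. Of 241 values of the counts and correlations, 221 stayed within 1.5 times, or within the jackknife error of a correlation. The alternatives added after the data were examined were the quantile step over locus-tag probes only, the offset of 0 for the agreement, means and overlaps of 3 hosts, genes with a mean above the random sets, and the division by array slopes. A 2-fold minimum lowered the counts by its own construction: to 1172 for the mean of 4 hosts, 1190 in Alnus glutinosa, 1158 in Alnus nepalensis, 1365 in Myrica gale, 1252 in Myrica rubra, 781 for genes changed in all 4 hosts, 174 for Alnus against Myrica, 640 for the F test, 88 between the Alnus hosts, 174 between the Myrica hosts and 584 in experiment B. Array weights raised the count between the Alnus hosts from 327 to 851; the cause was not tested. Leaving out 1 array gave 172 to 362 there; fewer arrays remained, and the lowest values came without Alnus glutinosa replicate 1 (214), 2 (192) or 3 (172) and Alnus nepalensis replicate 2 (208). Leaving out each array gave 2725 to 3138 for the mean of 4 hosts, 1103 to 1346 for Alnus against Myrica, and 1400 to 2106 in experiment B. With only the genes above single random probes on any array, 754 of 1083 genes were called in experiment B, since fewer genes were tested. Median scaling there moved the count from 2003 to 2180 and the share called higher from 53.7% to 65.5%; the cause was not tested. The Spearman rho between experiments rose from 0.611 to 0.653 without the genes in the lowest 25% of values in either experiment and to 0.721 over genes with a mean above the random sets, where the Pearson r was 0.767; the cause was not tested. Arrays of the same replicate number were not taken as pairs, since 8 of 30 pairs in experiment A and 1 of 3 in experiment B correlated above 0.1. Some did deviate together: replicates 3 of Alnus glutinosa, Alnus nepalensis and Myrica gale correlated between 0.231 and 0.278, and in 15 of 30 such comparisons in experiment A and 3 of 3 in experiment B an array correlated best with the array of its own number in the other group, a hint from the data and not from the design. The replicate number as a block gave 3139 genes for the mean of 4 hosts, 1392 for Alnus against Myrica and 2040 in experiment B, and moved no count by over 1.5 times. Centring on ribosomal protein genes and the gene lists were not run, for want of gene names. In experiment B signal over background sets the limit: 2699 genes were on no array above the random sets.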

Other observations

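Genes next to one another by locus number were called together more often than shuffled calls would give; this was examined after the data were seen. Of the 648 genes with FRAAL numbers called higher in all 4 hosts, 162 lay in runs of at least 4 neighbours, against a median of 0 and at most 17 in 1000 shuffles of the calls, and the longest run held 21 genes against 7. Besides the run with FRAAL6813, whose 21 genes were all called higher in experiment B too, runs of 15, 13, 12 and 10 genes rose. In experiment B 9 genes of the run of 13, 11 of the run of 12 and 10 of the run of 10 were called higher. Shorter runs varied, for example 1 of 5 genes from FRAAL5430 to FRAAL5435 and 5 of 5 from FRAAL5228 to FRAAL5233. The run of 15 had small changes, with a median log2 change of 1.16, and all 15 genes were called higher in experiment B. Of 984 genes called lower in all 4 hosts, 114 lay in such runs, against a median of 12 and at most 38, and their longest run, 8 genes, was no longer than the longest shuffled one. That locus numbers follow the order of genes on the chromosome was not tested.

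Differences between hosts ran together too. Of 747 genes with FRAAL numbers called higher in Alnus than in Myrica nodules, 99 lay in runs of at least 4, against at most 20 in 1000 shuffles, and of 591 called higher in Myrica 71 did, against at most 13. FRAAL3527 opened a run of 6 genes higher in Alnus, with log2 differences from 0.37 to 3.66. FRAAL5433 lay in a run of 5 genes higher in Myrica, with differences from -1.43 to -2.46. The longest such run, 11 genes, lies within the run that holds FRAAL6813; its Alnus minus Myrica differences were all between -0.62 and -0.42 (median -0.56, median SE 0.13). Once array slopes were divided out the median was -0.0042 (median SE 0.13), the differences lay between -0.35 and 0.07, and 0 of the 11 genes were called: the calls ended because the differences shrank, so this run is not evidence of a difference beyond the general stretch. Of all genes in such runs 97 of 99 higher in Alnus and 51 of 71 higher in Myrica stayed called; this was computed after the runs were seen.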
